A study of Mus musculus with 143 samples.

How the data were processed

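Lung tumours of 143 male mice were profiled, 1 tumour per mouse, on a 1-colour Agilent 4x180K array with several probes per gene. Per the labels the mice came from generation 4 of an intercross of A/J (the susceptible strain) and C57BL/6 (the resistant strain), received urethane at 1 g/kg at 4 weeks of age and were examined at 40 weeks. Each mouse carries a genotype at a marker, written here as A homozygous, heterozygous and B homozygous (A from A/J, B from C57BL/6), a batch and, for all but 1 mouse, its number of lung tumours. The labels give a mean RNA integrity number of 8.9 with an SD of 0.8 (the lowest was 6.7, the highest 9.9) and 100 ng of RNA per labelling reaction. They do not pair integrity numbers with mice.

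The scanner files exist for the 95 mice of batch 1 alone. Per the file headers their values are intensity, background-subtracted and detrended by Agilent Feature Extraction (version 10.7.3.1) with no normalization between arrays, beside other columns that hold flags of 0 or 1 per spot. The deposited value table covers all 143 mice and holds log2 intensity, normalized between arrays by the authors. The submitters' processing notes name Agilent Feature Extraction and limma, but the sources used here do not give the order of their steps. The scale, centring and direction of the table were therefore read from its values. It ran from -2.52 to 18.6, its column medians lay between 7.58 and 7.77, and its columns had a Spearman correlation of 0.984 to 0.989 across probes with the scanner values of the same mouse. In that table the mean of each probe was nearly equal in both batches (the largest difference was 0.0650, the SD over probes 0.00445, against a median standard error of 0.0553), so a test of batch 2 against batch 1 on it is void.

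Each scanner file holds 180880 spots, of which 172966 are not controls. Spots of a probe were averaged, which left 165984 probes, and 162395 of these (97.8%) were matched to a gene symbol through the array's transcript identifiers (21546 of 22483 matched). The log2 processed intensity minus the 75th percentile of its array was used. A probe was kept if it was well above background on at least 50% of the arrays of any genotype, and 138261 probes were. The gene value was the median of its kept probes (6 in the median gene, 1 in 2806 genes), which gave 17334 genes tested, 16631 of them with a symbol. The same probes in the deposited table gave 17174 genes. Named genes were chosen by a rule: in each test the 10 called genes of largest rise and the 10 of largest fall, called members of the distal chromosome 6 list with up to 10 others, and up to 4 members of smallest p per gene list. Transcripts without a gene symbol were passed over. A few genes that the rule or the lists name, and results that rest on them, are not reported here. The array was built on mm9, and chromosomes and the order of genes were taken from a table for GRCm38.p6, so no coordinates are given.

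The 75th percentile of intensity ranged from 325 to 1896 between arrays (log2 8.34 to 10.89), and 67.8% to 90.4% of probes (median 82.4%) were well above background. Both lowest values were those of 1 array, of a B homozygous tumour, called the dimmest array below. The next lowest 75th percentile was log2 9.60. No spot was saturated (0 spots). The arrays fill 24 slides of up to 4 arrays and were scanned on 4 days, and scan days and slides were tried as blocks. The highest correlation between 2 mice was 0.992 (median 0.975), and 0 columns were identical. The number of mice limits the precision of the values.

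Tests were fitted with limma (version 3.58.1, in R 4.3.3 with statmod 1.5.0, matrixStats 1.5.0 and the R package data.table, version 1.17.8) and moderated with eBayes. A gene is said to be called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of that test. The comparisons were the slope per A allele, each pair of genotypes, the deviation of heterozygous tumours from the mean of both homozygotes, and the slope per doubling of the tumour number with and without genotype in the model, in batch 1. In batch 2, A homozygous and heterozygous tumours were compared. Slopes per A allele and per doubling of the tumour number were also fitted over both batches of the deposited table with batch in the model. Tumour numbers were compared by two-sided permutation tests with 100000 resamples. Fisher's exact test, two-sided, compared the share of called genes on chromosome 6 with the rest. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3).

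A total of 27 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with fry beside it, each adjusted over the lists. The lists are distal chromosome 6 genes, RAS-MAPK output, alveolar type 2 cell, alveolar type 1 cell, club cell, ciliated cell, endothelial cell, fibroblast and matrix, smooth muscle and pericyte, heart muscle, adipocyte, red blood cell, macrophage, T and NK cell, B and plasma cell, neutrophil, cell division, MHC class II presentation, MHC class I presentation, interferon response, hypoxia and glycolysis, gastric differentiation of lung adenocarcinoma, lung tumour dedifferentiation, immediate early and heat shock genes (handling), oxidative phosphorylation, xenobiotic and redox defence, and cholesterol and fatty acid synthesis. A list's score is the mean of its members, each centred over arrays. The comparisons, lists, rule for named genes and first set of alternatives were fixed before the data were examined.

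The alternatives were quantile normalization, normexp background correction (offset 50) with quantile normalization, no filter, a filter on every array, the mean or the brightest probe in place of the median, the deposited table in place of the scanner files, slide as a fixed or random block, eBayes with trend and robust, other scales of the tumour number, the tumour number as a covariate, and fits without B homozygous mice or without the probe of largest change. The scanner files lack mean spot signals, so normexp used the median spot and median background signals. Chosen after seeing the data were scan day as a block, fits within each scan day, fits without the dimmest array, fits of genes by tumour number in single batches, and 2 kinds of covariate. One kind is the scores of cell type lists. The other is the receptor score, the mean of 318 olfactory and vomeronasal receptor genes of each array.

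The fits were tested on simulated data, with 200 genes changed in each of 10 draws and noise drawn independently for each gene and array. In the real data arrays of a slide were correlated (consensus 0.226 in the fit of the slope per A allele). The shares below, that of unchanged genes among calls included, need not hold there. For the slope per A allele, 62.3% of changes of 0.2 and 88.4% of changes of 0.4 (log2) were recovered, and 5.64% of calls were unchanged genes. For A homozygous against B homozygous the shares were 56.0% of changes of 0.4 and 94.6% of changes of 1. For the tumour number with genotype in the model they were 27.7% of slopes of 0.1 and 84.3% of slopes of 0.3. Copy number, mutation and methylation were not analysed here.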

Results

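Transcript levels were measured in 1 urethane-induced lung tumour from each of 143 mice on 1-colour arrays. By the genotype marker, 58 mice were A homozygous, 72 heterozygous and 13 B homozygous. Batch 1 held 95 mice (41 A homozygous, 41 heterozygous and all 13 B homozygous) and batch 2 held 48 (17 A homozygous and 31 heterozygous). Levels in batch 1 are log2 intensity relative to the 75th percentile of the array, which lay between 325 and 1896, with a median of 82.4% of probes well above background. Levels in batch 2, and in both batches together, are log2 values of the deposited table. The number of lung tumours was given for all but 1 mouse and ranged from 1 to 33.

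A first comparison asks whether the tumour number followed the marker. Each mouse gave a tumour for the array, so mice without a tumour are not among them. The numbers below hold for mice with at least 1 tumour. Mice with 2 A alleles carried the most tumours and mice with none the fewest: the mean was 16.6 ± 6.82 (SD, n = 57) in A homozygous, 11.1 ± 5.84 (SD, n = 72) in heterozygous and 2.08 ± 1.44 (SD, n = 13) in B homozygous mice. The difference between A and B homozygous mice was 14.5 tumours (SE 0.988), that between A homozygous and heterozygous mice 5.52 (SE 1.14) and that between heterozygous and B homozygous mice 9.02 (SE 0.796). Two-sided permutation tests gave an adjusted p of 1e-05 over the 3 pairs for each, the smallest that 100000 resamples can give. Within batch 1 the same differences were 15.6 (SE 1.19), 6.11 (SE 1.40) and 9.46 (SE 0.937). In batch 2, which held no B homozygous mice, A homozygous mice had 14.2 ± 5.69 tumours (SD, n = 17) and heterozygous mice 10.5 ± 6.38 (SD, n = 31), a difference of 3.66 (SE 1.79, permutation p = 0.0562) that did not pass the test. On the log2 scale the permutation p in batch 2 was 0.0239.

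**Figure D1:**
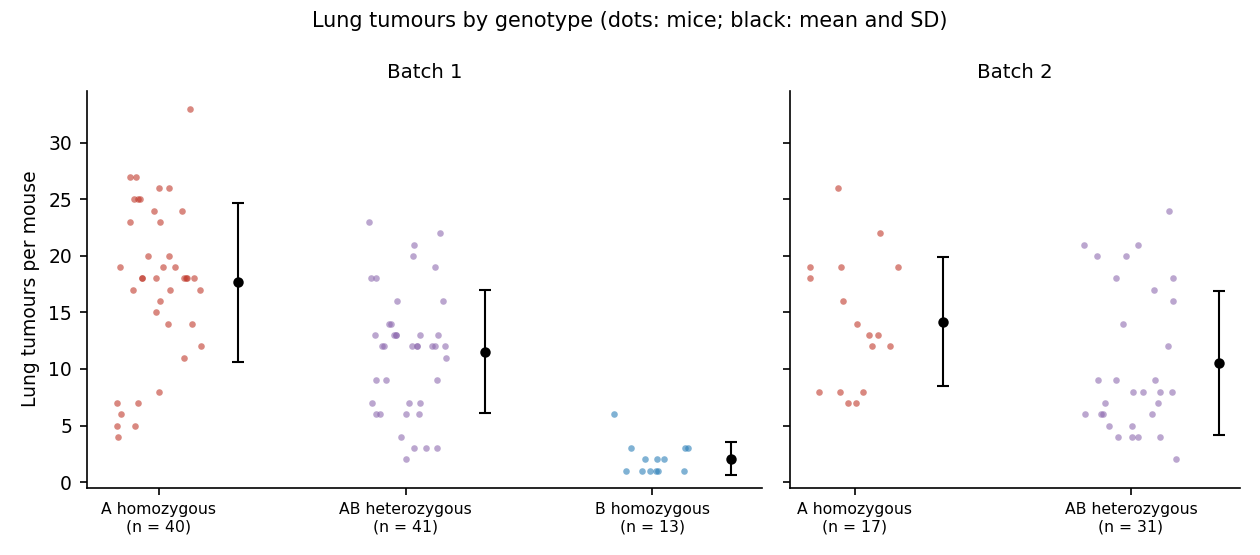
Number of lung tumours per mouse by genotype and batch; each point is 1 mouse, and lines give the mean and SD of a group. The mean in both batches together was 16.6 in A homozygous, 11.1 in heterozygous and 2.08 in B homozygous mice.

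The slope per A allele in batch 1 asks which transcripts followed the marker. Itpr2, an endoplasmic reticulum calcium channel on chromosome 6, rose by 0.49 (SE 0.0464, adjusted p = 1.68e-13), from -1.19 ± 0.335 (SD, n = 13) in B homozygous to -0.16 ± 0.330 (SD, n = 41) in A homozygous tumours. Ppfibp1, a liprin of the cell cortex, rose by 0.23 (adjusted p = 1.76e-13), while Fgfr1op2 had a slope of -0.31 (adjusted p = 2.67e-11). Rerg, a RAS-like gene known as an estrogen-regulated growth inhibitor, had a slope of -1.44 (adjusted p = 1.24e-09). Mgp, a matrix protein that inhibits calcification, lay at 5.55 ± 0.433 (SD, n = 41) in A homozygous and 6.66 ± 0.453 (SD, n = 13) in B homozygous tumours.

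Of the 41 measured genes of the distal chromosome 6 list, 6 were called higher and 12 lower with the A allele, and 23 were not called (7 higher and 13 lower adjusted over the list alone). Besides Itpr2 and Ppfibp1, rising members included Casc1 0.17, Ldhb 0.16 and Rep15 0.10. The falling members besides Fgfr1op2 were Pde3a -0.34, Arntl2 -0.26, St8sia1 -0.25, Rassf8 -0.22, Gys2 -0.21 and Tmtc1 -0.19, with Sox5 -0.17, Bcat1 -0.15, Tm7sf3 -0.15, Recql -0.13 and Golt1b -0.10. Pde3a is a cyclic nucleotide phosphodiesterase, Arntl2 a clock transcription factor, St8sia1 a sialyltransferase, Gys2 the liver glycogen synthase and Bcat1 a branched-chain aminotransferase. Against other genes the list did not pass camera (camera adjusted p = 0.225, and adjusted p = 0.646 with an estimated correlation), but it passed fry, which asks whether the members of a set move one way without regard to other genes (adjusted p = 0.00941). Its members had a median slope of -0.054. With the receptor score described below in the model, 4 were called higher and 4 lower (4 and 8 adjusted over the list alone), and the mean slope of the list, -0.048 (SE 0.0143) without it, was -0.013 (SE 0.0113). The slope of Casc1 turned to -0.089 with its brightest probe, that of Ldhb to -0.039 within scan day 1 and to -0.074 with the tumour number in the model. That of Rep15 turned to -0.0078 within scan day 2 and that of Tmtc1 to 0.0155 without B homozygous mice.

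The slope of Itpr2 was 0.47 with scan day as a block and 0.48 with slide as a block. Within scan days 1, 2 and 4 it was 0.44, 0.56 and 0.38, which passed the test on day 2 alone. Scan day 3 held no B homozygous mouse. By probes, of the 41 distal genes 12 had 2 or more kept probes and most of them called in the direction of the gene, 2 had 1 kept probe, which was called, and 16 had only some probes called. Probes were called in both directions in 6. All 55 kept probes of Itpr2 were called higher, as were 22 of 24 of Ppfibp1, with 2 called lower.

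**Figure D2:**
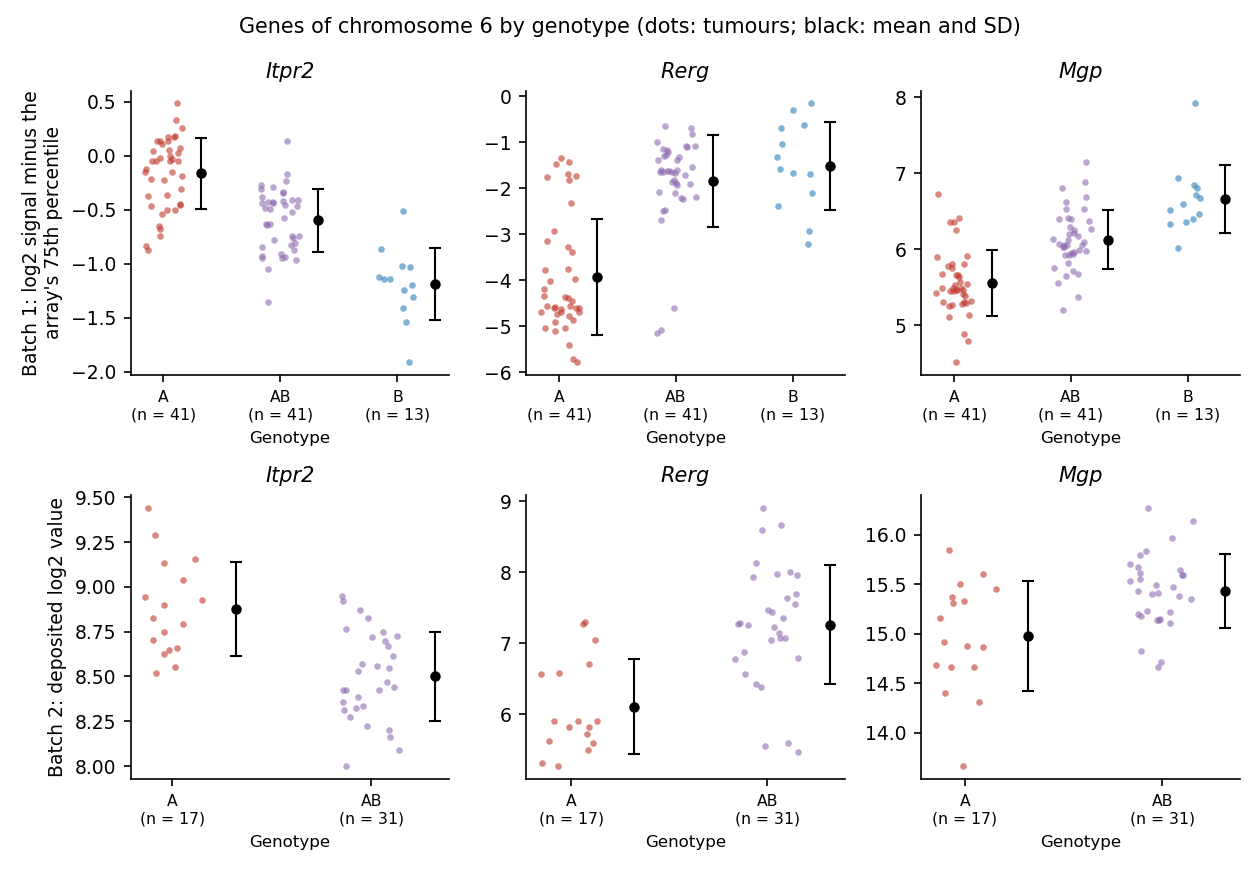
Levels of Itpr2, Rerg and Mgp in each tumour by genotype, as log2 intensity relative to the 75th percentile of the array in batch 1 and as deposited log2 values in batch 2; dots are tumours, black marks the mean and SD. Itpr2 lay at a mean of -0.16 in A homozygous and -1.19 in B homozygous tumours of batch 1.

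Called genes were denser on chromosome 6 than elsewhere. By the GRCm38.p6 table, 283 of its 875 tested genes were called (32.3%) against 27.7% on other chromosomes, an odds ratio of 1.25 (95% interval 1.07 to 1.45, Fisher's exact p = 0.00325).

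Across all genes, 4871 of 17334 were called by limma, 2118 higher and 2753 lower with the A allele. The higher and lower counts depended on the scaling: 2686 and 2393 with quantile normalization, 2519 and 2426 with normexp, and 2540 and 2320 in the deposited table. Of the 4871, 224 have no gene symbol. The largest rise was that of Klra3, a Ly49 natural killer receptor of a multigene family that varies between mouse strains (1.14, SE 0.171, adjusted p = 1.17e-06). It was followed by the kininogens Kng2 and Kng1 (1.11 and 0.88), the 20-alpha-hydroxysteroid dehydrogenase Akr1c18 (0.93), the cytochrome P450 gene Cyp2c40 (0.90) and albumin, Alb (0.87). Other large rises were those of Ypel4 (0.92), Ankrd22 (0.83), the imprinted Rtl1 (0.82) and Gdpd2 (0.81). With its brightest probe in place of the median the slope of Alb was -0.17. Among called genes the lowest slopes were mostly those of dim genes, many of them near background in A homozygous tumours, so their sizes and order are not exact. Pbp2 on chromosome 6, which rests on 1 probe, had -2.18 (SE 0.237, adjusted p = 2.67e-11) by scanner values and -1.27 in the deposited table. It was well above background on 17.1% of A homozygous, 87.8% of heterozygous and 92.3% of B homozygous arrays. Klra4, another Ly49 receptor, had a slope of -1.55. The vomeronasal receptors Vmn1r181 -1.77, Vmn1r122 -1.71 and Vmn1r139 -1.48 and the Y-linked spermatid gene Ssty1 (-1.60, well above background by at least 1 kept probe on 46.3%, 63.4% and 100% of the arrays of the 3 groups in the same order), with Gm10375 -1.58, Gm20747 -1.43 and BC061237 -1.42, had most of the other lowest slopes. In the deposited table Vmn1r181 had -1.10 and Ssty1 -1.02.

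Lymphocyte and interferon genes fell together with the A allele, mostly between B homozygous and heterozygous tumours. The T and NK cell mean differed by -1.003 (SE 0.192) from B homozygous to heterozygous and by -0.091 (SE 0.133) from heterozygous to A homozygous tumours. For the interferon mean these steps were -0.75 (SE 0.187) and -0.17 (SE 0.130). Of 21 measured T and NK cell markers, 17 were called lower, 0 higher and 4 not called (20 lower adjusted over the list alone). Among them were the T cell co-receptor chains Cd8b1 (-0.71, SE 0.128, adjusted p = 4.63e-05) and Cd8a (-0.51), the natural killer receptor Ncr1 (-0.68) and the granule gene Nkg7 (-0.67). The set passed camera but not with an estimated correlation (camera adjusted p = 1.32e-09, and adjusted p = 0.359 with an estimated correlation). Of 12 B and plasma cell markers 11 were lower (12 adjusted over the list alone), such as Cd79a -0.45, Tnfrsf17 -0.51 and Ms4a1 -0.77 and the transcription factor Pax5 -0.23 (camera adjusted p = 7.34e-06, and adjusted p = 0.359 with an estimated correlation). Interferon response genes were lower in 21 of 23 cases (22 adjusted over the list alone), with Ifit2 -0.51, Ifit3 -0.34 and Stat2 -0.25 (camera adjusted p = 5.12e-10, and adjusted p = 0.359 with an estimated correlation). For MHC class I presentation 12 of 15 were lower over all genes and adjusted over the list alone, including the immunoproteasome subunit Psmb9 (-0.45) and the light chain B2m (-0.30) (camera adjusted p = 1.62e-05, and adjusted p = 0.393 with an estimated correlation). The mean slope of the T and NK cell list, -0.43, was -0.39 with scan day as a block and -0.20, -0.62 and -0.66 within scan days 1, 2 and 4. That of the interferon list, -0.38, was -0.36 with scan day as a block and -0.27, -0.50 and -0.53 within scan days 1, 2 and 4.

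Vessel, alveolar type 1 and red blood cell genes fell as well, again mostly between B homozygous and heterozygous tumours. The endothelial mean differed by -0.54 (SE 0.115) in that step and by -0.042 (SE 0.0799) from heterozygous to A homozygous tumours. Endothelial markers were lower in 13 of 19 cases (14 adjusted over the list alone; Pecam1 -0.32, Cdh5 -0.32, Tek -0.34 and Ramp2 -0.39), and their mean slope of -0.22 was -0.23 with scan day as a block and -0.14, -0.40 and -0.33 within scan days 1, 2 and 4 (camera adjusted p = 4.45e-06, and adjusted p = 0.359 with an estimated correlation). Of 13 alveolar type 1 markers, which line the gas-exchange surface, 11 were lower on both counts (Cav1 -0.47, Hopx -0.40, Emp2 -0.22 and Gprc5a -0.17; camera adjusted p = 0.000154, and adjusted p = 0.359 with an estimated correlation). Among 8 red blood cell genes, 5 were lower on both counts, including the globins Hba-a1 (-0.62), Hbb-bt (-0.54) and Hba-a2 (-0.37) (camera adjusted p = 0.00342, and adjusted p = 0.359 with an estimated correlation). Neutrophil genes had 3 of 12 lower, namely Retnlg -0.66, Camp -0.45 and Il1b -0.31, again on both counts (camera adjusted p = 0.0289, and adjusted p = 0.589 with an estimated correlation). Fibroblast and matrix genes had 6 of 16 lower (8 adjusted over the list alone), with Mfap4 -0.61, Inmt -0.59, Pdgfra -0.32 and Tcf21 -0.48, but the set did not pass camera (adjusted p = 0.0655).

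RAS-MAPK output genes, the feedback regulators and targets of RAS signalling, rose: 9 of 20 were called higher and 0 lower (10 higher adjusted over the list alone). Examples were the phosphatase Dusp4 (0.31, SE 0.0523, adjusted p = 2.17e-05), the feedback inhibitor Spry2 (0.23), the receptor Epha2 (0.27) and the ETS factor Etv4 (0.30). The set had camera adjusted p = 7.14e-06, and adjusted p = 0.359 with an estimated correlation. The mean slope of the list, 0.15, was 0.14 with scan day as a block and 0.11, 0.10 and 0.25 within scan days 1, 2 and 4. Its mean differed by 0.28 (SE 0.0802) from B homozygous to heterozygous and by 0.074 (SE 0.0556) from heterozygous to A homozygous tumours. Lung tumour dedifferentiation genes had 6 of 18 higher and 1 lower (7 and 1 adjusted over the list alone). The tight junction gene Cldn2 (0.79) and the lung lineage factors Nkx2-1 (0.12) and Foxa2 (0.14) rose and Vim fell (-0.21), and the set did not pass camera (adjusted p = 0.0549). Nkx2-1 and Foxa2 are known as keepers of lung identity.

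None of the other lists passed camera (adjusted p from 0.0582 to 0.696). Fry called 14 of the 27 lists: the 9 that camera called, distal chromosome 6, fibroblast and matrix (adjusted p = 0.00681), dedifferentiation (adjusted p = 0.00941), immediate early and heat shock (adjusted p = 0.0223) and club cell genes (adjusted p = 0.0378). Alveolar type 2 genes had 4 of 18 higher and 1 lower, with Muc1 (0.22), the phosphate transporter Slc34a2 (0.14) and the surfactant protein Sftpd (0.10). Oxidative phosphorylation had 8 of 27 higher and 2 lower (Atp5a1 0.13 and Uqcrc1 0.15), and cholesterol and fatty acid synthesis had 4 of 22 higher, namely Srebf1 0.18, Fasn 0.20, Acly 0.11 and Me1 0.21. Immediate early and heat shock genes had 4 of 17 higher (Ier2 0.24, Junb 0.20, Hspa1a 0.42 and Egr1 0.26), hypoxia and glycolysis 3 of 23 higher and 2 lower (Ldha 0.18, Pfkl 0.19 and Vegfa -0.19), and xenobiotic and redox defence 3 of 23 higher and 2 lower (Cat 0.22, Hmox1 0.17 and Cyp2e1 -0.61). Lower members were 3 of 14 club cell genes (Cyp2b10 -0.60, Aldh1a1 -0.26 and Cyp2f2 -0.42), 2 of 15 ciliated cell genes (Tppp3 -0.42 and Dnah11 -0.20) and 2 of 11 MHC class II genes (H2-Oa -0.61 and H2-Ob -0.58). So were 1 of 17 macrophage genes (Adgre1 -0.16), 1 of 30 cell division genes (Rrm2 -0.16) and 1 of 8 adipocyte genes (Cidec -0.45). Smooth muscle and pericyte genes had 1 of 12 higher and 2 lower (Rgs5 0.31, Des -0.23 and Myh11 -0.29), and heart muscle 2 of 10 higher (Myh7 0.39 and Myh6 0.35). By limma 0 of 13 genes of gastric differentiation were called, Cldn18 having the smallest p (0.12, SE 0.0581, adjusted p = 0.126). Adjusted over the list alone, the counts of these lists were within 1 of those over all genes.

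**Figure D3:**
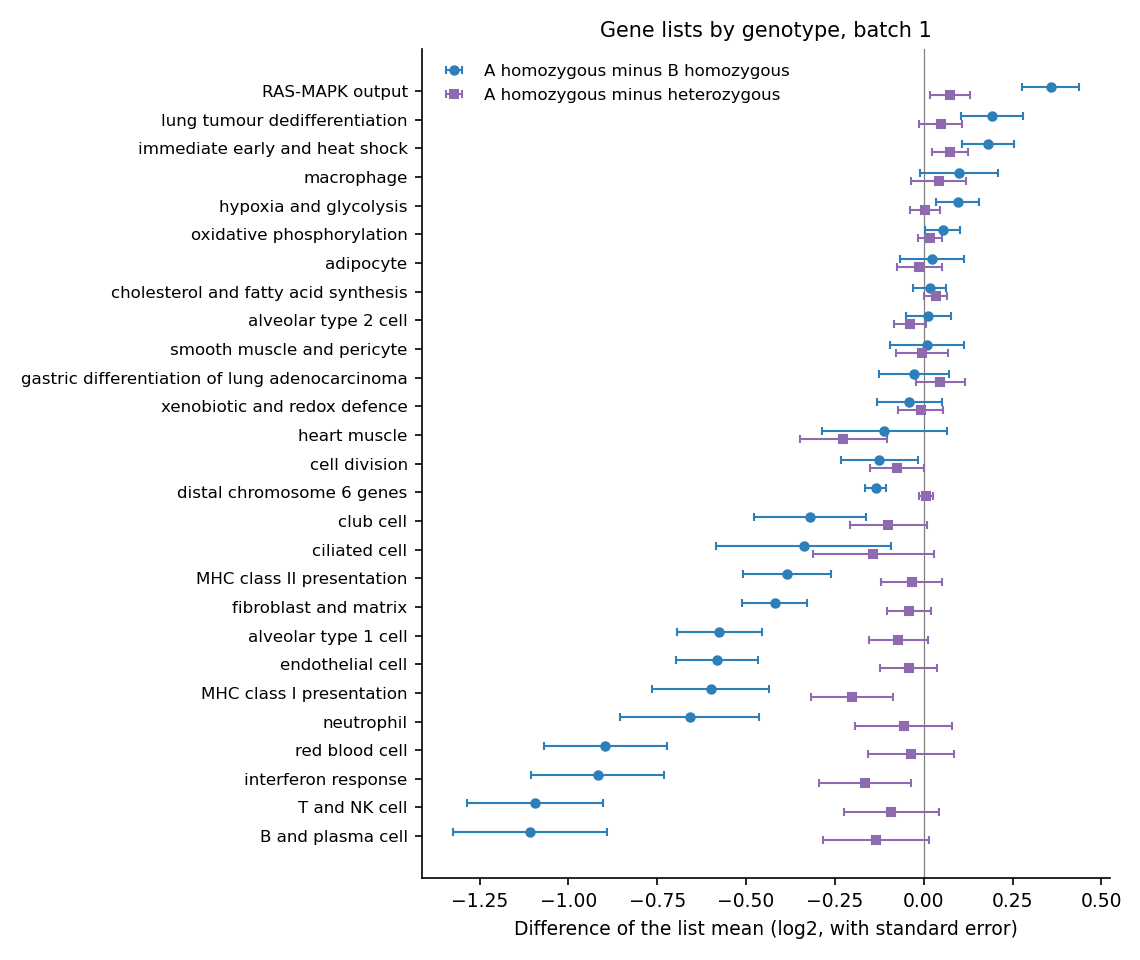
Difference of the mean of each gene list between genotypes in batch 1, in log2: circles are A homozygous minus B homozygous tumours, squares A homozygous minus heterozygous tumours, and bars the standard error. The T and NK cell list lay at -1.09 and RAS-MAPK output at 0.36 between A and B homozygous tumours.

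Receptors of smell moved with these groups. Of 318 measured olfactory and vomeronasal receptor genes, which serve the nose, 176 were lower in A homozygous than in B homozygous tumours and 0 higher. These were 104 of 207 Olfr genes (median -0.40), 25 of 37 Vmn1r genes (median -0.65) and 47 of 74 Vmn2r genes (median -0.62). The families were chosen after the data were seen. The filter could favour lower values, in the score below as well, since a dim receptor could be kept through the B homozygous arrays alone. The other scalings here used the same filter. Under the other scalings their medians stayed below 0 but were smaller, in the same order -0.27, -0.52 and -0.47 with quantile normalization, -0.12, -0.23 and -0.23 with normexp and -0.20, -0.36 and -0.30 in the deposited table, with 127 lower and 3 higher under quantile normalization, 118 and 3 under normexp and 115 and 3 in the deposited table. The receptor score, their mean, was -0.14 ± 0.50 (SD, n = 41) in A homozygous, -0.021 ± 0.495 (SD, n = 41) in heterozygous and 0.49 ± 0.39 (SD, n = 13) in B homozygous tumours. The A homozygous minus B homozygous difference was -0.63 (SE 0.154, permutation adjusted p = 2.10e-04), and -0.38, -0.60 and -0.64 within scan days 1, 2 and 4. With this score in the model, 1250 genes followed the A allele (647 higher and 603 lower, 1218 shared with the 4871). Of the lists above, 9 T and NK cell (15 adjusted over the list alone), 1 B and plasma cell (10), 11 interferon response (18), 7 MHC class I (12), 7 endothelial (10), 4 alveolar type 1 (7) and 1 red blood cell gene (5) were lower and 3 RAS-MAPK genes (8) higher. Neutrophil and fibroblast genes had 1 (1) and 2 (5) lower and dedifferentiation and oxidative phosphorylation genes 1 (3) and 1 (2) higher, and of the other lists but the distal one none kept over 3 called genes. Without and with the score the mean slope was -0.43 (SE 0.0940) and -0.30 (SE 0.0935) for T and NK cell, -0.44 (SE 0.104) and -0.33 (SE 0.106) for B and plasma cell, -0.38 (SE 0.0886) and -0.28 (SE 0.0906) for interferon and 0.15 (SE 0.0377) and 0.11 (SE 0.0382) for RAS-MAPK output genes. With the tumour number in the model 34 genes were called, and without B homozygous mice 17. Within scan days 1, 2 and 4 the counts were 1, 1563 and 13, and with scan day as a block 3952.

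Between A homozygous and B homozygous tumours of batch 1, the widest marker contrast, lymphocyte, interferon, vessel and blood genes were lower and RAS output genes higher in A homozygous tumours. All 21 T and NK cell genes, all 12 B and plasma cell genes and all 23 interferon response genes were called lower over all genes and adjusted over the list alone. The mean of the T and NK cell list differed by -1.09 (SE 0.192). All 13 B homozygous tumours lay above the A homozygous median, as they did for the interferon list (-0.92, SE 0.187), the red blood cell list (-0.90, SE 0.174) and the fibroblast list (-0.42, SE 0.0905). RAS-MAPK output differed by 0.36 (SE 0.0802), with 11 of 20 genes higher and 2 of 13 B homozygous tumours above the A homozygous median. The list of immediate early and heat shock genes (handling) differed in the same direction, by 0.18 (SE 0.0726). Whether handling bears on both was not tested.

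Single genes spanned large ranges. The natural killer receptor gene Ncr1 differed by -1.75 (SE 0.242, adjusted p = 1.02e-07), Cd8b1 by -1.73, the B cell gene Ms4a1 by -1.98 and the interferon-induced Usp18 by -1.33. Endothelial genes had 14 of 19 lower (17 adjusted over the list alone; Pecam1 -0.78, Tek -0.89 and Cldn5 -1.22), alveolar type 1 genes 11 of 13 (12; Cav1 -1.19 and Emp2 -0.48) and red blood cell genes 6 of 8 (7; Hba-a1 -1.57 and Alas2 -1.26). Among RAS-MAPK genes Dusp4 0.74, Epha2 0.65, Spry2 0.55 and Spred1 0.51 were higher. Camera called 12 of the 27 lists and 0 with an estimated correlation (smallest adjusted p = 0.289), and fry called 14. The receptor score moved with these groups: with it in the model the T and NK cell difference was -0.83 (SE 0.197) and the RAS-MAPK difference 0.26 (SE 0.0833). With endothelial and alveolar type 1 scores in the model in its place they were -0.74 (SE 0.199) and 0.17 (SE 0.0792). With the receptor score 14 T and NK cell (19 adjusted over the list alone), 11 B and plasma cell (12), 15 interferon (21), 12 endothelial (15), 6 alveolar type 1 (12), 5 red blood cell (5) and 8 RAS-MAPK genes (9) were called.

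In the distal chromosome 6 list 6 genes were higher and 14 lower (7 and 16 adjusted over the list alone), and 3 and 8 (4 and 11) with the receptor score in the model. The mean of the list differed by -0.14 (SE 0.0290), by -0.057 (SE 0.0237) with that score and by -0.070 with quantile normalization, -0.037 with normexp and -0.064 in the deposited table. The smallest p were those of Itpr2 1.02, Ppfibp1 0.50 and Fgfr1op2 -0.71. The largest rises were Klra3 2.47, Kng2 2.46, Cyp2c40 2.29, Ypel4 2.27 and Akr1c18 2.08, Alb 2.00, Ankrd22 2.00, Cyp2c68 1.98 and Rtl1 1.90 and the tight junction gene Cldn2 1.86. The lowest differences of called genes were Vmn1r181 -3.81, Ssty1 -3.67, Pbp2 -3.66, Vmn1r122 -3.65 and Gm10375 -3.40 and Klra4 -3.34, Gm20747 -3.32, Vmn1r139 -3.21, BC061237 -3.18 and Vmn1r183 -3.02. These 10 were well above background, by at least 1 kept probe, on 17.1% (Pbp2) to 46.3% of A homozygous arrays, so their sizes and order depend on values near background. In the deposited table Pbp2 had -2.10 and Vmn1r181 -2.39. With the brightest probe Alb had -0.39 and Casc1 -0.20.

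The test called 6005 of 17334 genes, 2376 higher and 3629 lower (271 without a symbol), and 2323 (1003 and 1320, 2261 of them shared) with the receptor score in the model. The higher and lower counts depended on the scaling: 3064 and 2918 with quantile normalization, 2899 and 2997 with normexp, and 2906 and 2855 in the deposited table. Called dim genes were mostly lower. Of the 3466 genes of lowest mean level 139 were higher and 1057 lower, and of the 3467 of highest mean level 719 and 360. The filter could favour this, since a dim gene could be kept through the B homozygous arrays alone. Counts within scan days 1, 2 and 4 were 0 (835 with an unadjusted p under 0.05 by limma), 1866 and 2765, and with scan day as a block 5264.

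A homozygous and heterozygous tumours can be compared in both batches, in separate mice. Scanner values exist for batch 1 alone, and the deposited table, where differences at several of these genes were smaller than by scanner values, covers both. They differed mainly at genes of chromosome 6. By scanner values Itpr2 was higher in A homozygous tumours of batch 1 by 0.43 (adjusted p = 3.63e-05). In the deposited table it was higher by 0.39 in batch 1 and 0.38 in batch 2 (p = 9.71e-06 in batch 2), with 35 of 41 (scanner values) and 17 of 17 A homozygous tumours above the heterozygous median. In the same order, scanner value in batch 1 and then the deposited values of batches 1 and 2, Magohb, of the exon junction complex, had 0.30, 0.31 and 0.32 (39 of 41 and 15 of 17 above that median) and Ppfibp1 0.19, 0.24 and 0.15 (39 and 12). Rerg had -2.09, -1.46 and -1.15, with 3 of 41 and 2 of 17 above that median, and Mgp -0.57, -0.55 and -0.46 (5 and 4).

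The other genes of chromosome 6 called lower in batch 1, with their values in that order, were Pbp2 (-3.17, -1.87 and -1.32), the protease inhibitor gene A2ml1 (-1.42, -1.07 and -0.43) and the Ly49 receptors Klra4 (-1.22, -0.64 and -0.41) and Klra7 (-1.05, -0.57 and -0.42). Also lower were the class II phosphatidylinositol kinase Pik3c2g (-0.87, -0.58 and -0.17), Gsg1 (-0.47, -0.35 and -0.23) and Emp1 (-0.43, -0.39 and -0.086). Pbp2 and Klra4 rest on 1 probe each, well above background on 17.1% and 19.5% of A homozygous arrays, and of the values of the 4 probes of Klra7 39.02% were, so the size of these differences is not exact. On other chromosomes, in the same order, Zfp523 (0.27, 0.27 and 0.048), 3110082I17Rik (0.17, 0.15 and 0.10) and Tmem161a (0.11, 0.11 and 0.058) were called higher in batch 1 and Fbxw13 (-0.77, -0.50 and -0.068) and Siah3 (-0.38, -0.35 and -0.46) lower. Of these 5 only Siah3 had an unadjusted p under 0.05 in batch 2 (p = 0.00110; the lowest of the others was 0.157). With the brightest probe Klra7 had 0.0366 and Tmem161a -0.0570.

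In batch 1 limma called 19 of 17334 genes, 6 higher and 13 lower (2 without a symbol), with 1337 at an unadjusted p under 0.05. On chromosome 6, 12 of 875 tested genes with a known position were called against 5 of 15756 elsewhere (odds ratio 43.8, 95% interval 14.3 to 158, Fisher's exact p = 2.03e-12). With scan day as a block 23 genes were called, with slide as a block 15, with the receptor score 18 and within scan days 1 to 4 0 (139 at an unadjusted p under 0.05), 1, 0 (536) and 3. In batch 2 limma called 0 of 17174 genes (609 at an unadjusted p under 0.05). The smallest adjusted p were those of Itpr2 and Rerg (0.0834 each), followed by Pbp2, Fgfr1op2 (-0.30), B3gnt6 (0.31) and Magohb. Of the 19 genes of batch 1, 18 had the same sign in batch 2 and 11 an unadjusted p under 0.05 there. Adjusted over these 19 alone, those that passed limma in batch 2 were Itpr2 and Rerg (adjusted p = 9.22e-05 each), Pbp2 (1.93e-04), Magohb (6.63e-04), Mgp and Siah3 (0.00350 each) and Klra7 (0.0395). The others did not pass.

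**Figure D4:**
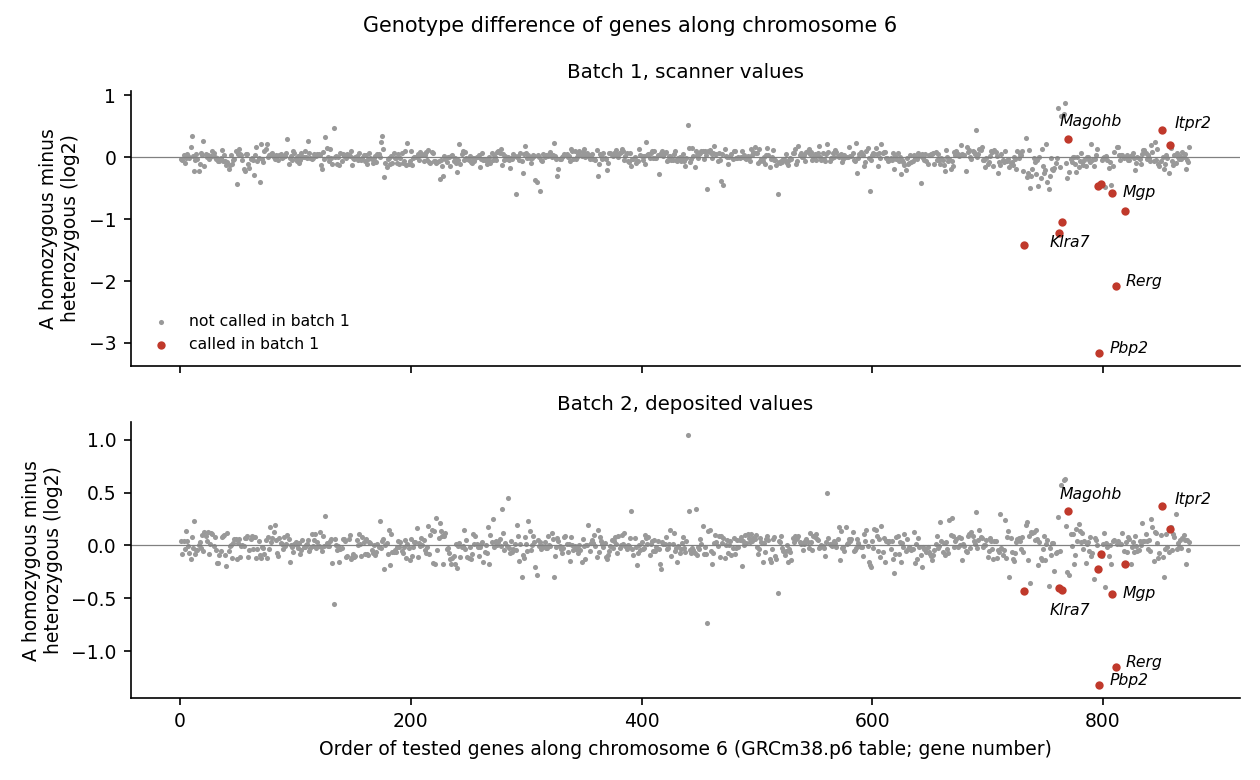
Genes of chromosome 6 in their order by the GRCm38.p6 table against the log2 difference of A homozygous minus heterozygous tumours in each batch; red dots are genes called in batch 1, 6 of them named. Itpr2 lay at 0.43 in batch 1 and 0.38 in batch 2.

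By gene lists, limma called 0 members outside the distal list between A homozygous and heterozygous tumours in either batch. Camera called 6 lists in batch 1, all with lower means in A homozygous tumours: MHC class I presentation at -0.20 (adjusted p = 6.10e-06, and adjusted p = 0.864 with an estimated correlation), interferon response at -0.17 (adjusted p = 7.54e-05, and adjusted p = 0.864 with an estimated correlation) and cell division at -0.075 (adjusted p = 0.00216, and adjusted p = 0.864 with an estimated correlation). The others were heart muscle at -0.23 (adjusted p = 0.0178, and adjusted p = 0.864 with an estimated correlation), ciliated cell at -0.14 (adjusted p = 0.0211, and adjusted p = 0.864 with an estimated correlation) and alveolar type 1 cell at -0.072 (adjusted p = 0.0362, and adjusted p = 0.864 with an estimated correlation). In batch 2 it called 6: ciliated cell at 0.35 (adjusted p = 3.76e-09, and adjusted p = 0.221 with an estimated correlation), xenobiotic and redox defence at 0.19 (adjusted p = 1.49e-05, and adjusted p = 0.0785 with an estimated correlation) and club cell at 0.33 (adjusted p = 0.00359, and adjusted p = 0.221 with an estimated correlation). It also called MHC class I presentation at -0.13 (adjusted p = 0.00359, and adjusted p = 0.731 with an estimated correlation), hypoxia and glycolysis at -0.066 (adjusted p = 0.00359, and adjusted p = 0.282 with an estimated correlation) and alveolar type 2 cell at -0.063 (adjusted p = 0.0113, and adjusted p = 0.388 with an estimated correlation). Adjusted over the list alone, 4 xenobiotic defence genes, the glutathione enzymes Gstm1, Gstm2, Gstm3 and Gpx2 (0.50, 0.48, 0.46, 0.62), were higher in batch 2. Of the 10 lists that camera called in either batch 7 had means of opposite signs in the batches, and MHC class I presentation, interferon response and alveolar type 2 cell were lower in both. The club cell mean in batch 1 was -0.099 and the xenobiotic defence mean -0.0090. No list passed fry in either batch (smallest adjusted p = 0.738 in batch 1 and 0.0550 in batch 2).

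Heterozygous tumours, with 1 A allele, were compared with B homozygous tumours in batch 1. T and NK cell genes were lower in heterozygous tumours in 20 of 21 cases (21 adjusted over the list alone; Ncr1 -1.62, Tbx21 -1.29, Cd8b1 -1.43 and Cd2 -1.34), and B and plasma cell genes in 11 of 12 (12; Ms4a1 -1.79). Interferon genes were lower in 21 of 23 (23; Ifit1 -1.01 and Usp18 -1.13), endothelial genes in 14 of 19 (16; Tek -0.85 and Cldn5 -1.11) and red blood cell genes in 6 of 8 (7). RAS-MAPK genes were higher in 9 of 20 cases (10; Dusp4 0.62, Spred1 0.50 and Epha2 0.53), and the malic enzyme gene Me1 by 0.73. The distal chromosome 6 list had 4 genes higher and 12 lower (4 and 15 adjusted over the list alone), with Fgfr1op2 -0.52, Itpr2 0.59, Ppfibp1 0.31 and St8sia1 -0.63.

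The largest rises in heterozygous tumours were Cyp2c40 2.09, Ypel4 1.95, Cyp2c68 1.90, Bex4 1.74 and Ros1 1.72, a receptor tyrosine kinase, and Bex1 1.71, Kng2 1.67, Spag11b 1.65, Ankrd22 1.61 and Klra3 1.59. The lowest differences of called genes, most of them of the same dim genes and no more exact, were Ssty1 -2.73, Gm20747 -2.53, Vmn1r181 -2.43, Gm20806 -2.30 and Vmn1r122 -2.25, BC061237 -2.24, Gm10375 -2.13, Klra4 -2.11 and Vmn1r139 -2.11 and the secreted phospholipase Pla2g5 -2.06. limma called 4088 genes, 1276 higher and 2812 lower (195 without a symbol). The split was 1805 and 2074 with quantile normalization, 1613 and 2164 with normexp, and 1652 and 2065 in the deposited table. Camera called 13 lists, and 0 with an estimated correlation (smallest adjusted p = 0.311), and fry called 11. The receptor score differed by -0.52 (SE 0.154), and with it in the model 1438 genes were called (450 higher and 988 lower). With it 13 T and NK cell (18 adjusted over the list alone), 7 B and plasma cell (12), 8 interferon (17), 10 endothelial (15) and 5 red blood cell genes (5) were called lower. Of RAS-MAPK genes 3 were higher (8 higher and 1 lower adjusted over the list alone), and the distal chromosome 6 list had 2 higher and 8 lower (3 and 10). The mean difference of the T and NK cell and interferon lists was -1.003 (SE 0.192) and -0.75 (SE 0.187) without and -0.79 (SE 0.192) and -0.58 (SE 0.191) with the score. Within scan days 1, 2 and 4 the counts were 0 (805 at an unadjusted p under 0.05), 0 (3823) and 1675, and with scan day as a block 4023.

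Heterozygous tumours were also compared with the midpoint of the homozygotes. Here limma called 187 genes, 41 higher and 146 lower (6 without a symbol). Without the dimmest array, which is that of a B homozygous tumour, it called 0 (2717 at an unadjusted p under 0.05). With the receptor score in the model it called 0 as well (2084). Among the lowest were Cd2, an adhesion molecule of T and NK cells (-0.78, SE 0.174, adjusted p = 0.0301), Ncr1 (-0.75), the B cell inhibitory receptor Siglecg (-0.68) and the transcription factor Tbx21 (-0.67). Others were Tmem132d -1.10, Vsnl1 -0.75, Rab39 -0.73, Rab30 -0.69 and Bfsp2 -0.66 and the platelet tubulin Tubb1 -0.70. Above the midpoint were Pbp2, whose midpoint rests on 1 probe near background in most A homozygous tumours so that its value (1.34) is not exact, Bex4 (0.85), Ros1 (0.79) and the mitochondrial coactivator Ppargc1a (0.42). So were malic enzyme Me1 (0.41), the bicarbonate transporter Slc4a4 (0.41) and Nipal1 0.40, Slc16a7 0.39, Zfp385b 0.35 and Tc2n 0.34. With quantile normalization 29 genes were higher and 22 lower, and with scan day as a block 344 were called. Gene lists were not tested against the midpoint.

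The next comparisons ask which transcripts followed the number of tumours in the lung of the mouse. In batch 1 with genotype in the model, 4 genes did. The autophagy gene Map1lc3a rose by 0.16 (SE 0.0342, adjusted p = 0.0327) per doubling of the number, while the RSK family kinase Rps6ka6 had -0.29 (SE 0.0545, adjusted p = 0.0134), the glycoprotein folding sensor Uggt2 -0.21 (SE 0.0426, adjusted p = 0.0327) and the lipid phosphatase Mtmr4 -0.11 (SE 0.0228, adjusted p = 0.0497). In batch 2 their slopes were 0.069, -0.059, -0.0020 and 0.019 (p = 0.214, 0.445, 0.955 and 0.483), and none passed there. limma gave 2190 genes at an unadjusted p under 0.05. With the receptor score in the model 46 genes were called (36 higher and 10 lower), with scan day as a block 7 and with slide as a fixed block 0 (1594).

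In the same test limma called 0 members of any gene list over all genes. Camera called 5: neutrophil at a mean slope of -0.20 (adjusted p = 1.51e-05, and adjusted p = 0.445 with an estimated correlation), cholesterol and fatty acid synthesis at -0.047 (adjusted p = 0.000433, and adjusted p = 0.445 with an estimated correlation) and oxidative phosphorylation at 0.034 (adjusted p = 0.000433, and adjusted p = 0.960 with an estimated correlation). The others were T and NK cell at -0.092 (adjusted p = 0.00309, and adjusted p = 0.960 with an estimated correlation) and B and plasma cell at -0.13 (adjusted p = 0.00309, and adjusted p = 0.960 with an estimated correlation). No list passed fry (smallest adjusted p = 0.196). Adjusted over the list alone, 4 neutrophil genes were lower, among them the calprotectin subunits S100a9 (-0.51) and S100a8 (-0.41), and 4 cholesterol genes, including Lss -0.10, Cyp51 -0.13 and Idi1 -0.14, while the club cell gene Cbr2 was higher (0.57). Over the list alone and with the receptor score in the model, limma called 0 neutrophil genes (5 at an unadjusted p under 0.05) and 1 cholesterol gene lower. Camera called 5 lists with that score, all lower and 3 of them among those above, while T and NK cell (-0.043) and oxidative phosphorylation (0.028) lost the call. With quantile normalization and with normexp the oxidative phosphorylation mean was 0.00312 and 0.00307, and its direction in camera turned. With slide as a fixed block camera again called 5 lists, but of the 5 above only oxidative phosphorylation (0.0355). The means of the others were -0.0362 for neutrophil, -0.0128 for cholesterol and fatty acid synthesis and -0.0204 for B and plasma cell, and the T and NK cell mean was 0.0334.

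Without genotype in the model, the largest rises with the tumour number were Kng2 0.57, Spag11b 0.54, Ypel4 0.45, Klra3 0.45 and Nrn1 0.44, and Ptn 0.42, Bex4 0.42, Kng1 0.41, Bex2 0.41 and Ccn3 0.40. The lowest slopes, mostly of the same dim genes, were Ssty1 -1.08, Vmn1r181 -1.06, Vmn1r122 -1.05, Gm20747 -0.97 and Vmn1r139 -0.93, and Gm10375 -0.91, Vmn1r183 -0.87, Gm20806 -0.87, BC061237 -0.86 and Gm5891 -0.77. Ptn and Nrn1 code for secreted growth factors of nerve cells. In all 4947 genes were called, 2039 higher and 2908 lower (215 without a symbol), and 2764 and 2509 with quantile normalization. With the receptor score there were 2036. Within scan days 1 to 4 the counts were 0 (2583 at an unadjusted p under 0.05), 98, 0 (2013) and 2026, with scan day as a block 4860 and with slide as a fixed block 2683 (928 higher and 1755 lower). Within scan day 3 Spag11b, Ypel4 and Klra3 had slopes of -0.50, -0.48 and -0.26, and within day 1 Nrn1 had -0.18.

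For the difference of this slope between A homozygous and heterozygous mice of batch 1, limma called 0 genes (1614 at an unadjusted p under 0.05). Within scan day 4 it called 428, 244 higher and 184 lower, and within days 1 to 3 it called 0 (765, 559 and 719). The smallest p were those of the integrin Itga5 (0.26, SE 0.0644), the sodium-calcium exchanger Slc8a1 (0.45) and Rin3 (0.24), and below 0 of Zfp260 (-0.21), Mbd5 (-0.19) and Akr1c12 (-0.54), with an adjusted p of 0.480 for Itga5.

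Over both batches of the deposited table, cholesterol synthesis genes fell with the tumour number within genotype and batch, and the club cell gene Cbr2 and the cell division kinase Aurkb rose. Of 22 cholesterol and fatty acid synthesis genes 4 were lower (9 adjusted over the list alone): the isoprenoid enzymes Idi1 (-0.18, SE 0.0388, adjusted p = 0.00726) and Fdps (-0.15) and the sterol enzymes Cyp51 (-0.15) and Sqle (-0.19). Camera called the list at -0.065 (adjusted p = 3.24e-08, and adjusted p = 0.0438 with an estimated correlation), and so did fry (adjusted p = 0.00177). In batch 1 camera did not call this list with slide as a fixed block, as given above. Slides are known for batch 1 alone, so the fit over both batches could not include them. Neutrophil genes had a mean of -0.14 (adjusted p = 7.82e-05, and adjusted p = 0.563 with an estimated correlation) with S100a9 -0.43 and S100a8 -0.36, neither called. Red blood cell genes had -0.12 (adjusted p = 0.0247, and adjusted p = 0.953 with an estimated correlation), and cell division genes 0.054 (adjusted p = 0.000290, and adjusted p = 0.953 with an estimated correlation), where Aurkb was called (0.11, adjusted p = 0.0213). In batch 1 alone (scanner values) and batch 2 alone, Idi1 had -0.14 and -0.29 and Cbr2 0.57 and 0.24, none of which passed the test over all genes. Among single genes the carbonyl reductase Cbr2 rose by 0.44 (SE 0.118, adjusted p = 0.0282), Siglecf, a receptor of eosinophils and alveolar macrophages, by 0.19 (adjusted p = 0.0441), and the chromatin protein Hmga2 by 0.12 (adjusted p = 0.0259).

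The other largest rises were Pcdhga2 0.38, Adra2c 0.37, Pnliprp1 0.30, Spata20 0.24 and Mef2b 0.22 and Olfr9 0.20, Rapgef5 0.19 and Cuedc1 0.18. The largest falls were Ssty1 (-0.52), Rnase10 (-0.36), the mast cell tryptase Tpsb2 (-0.25), the glucose transporter Slc2a10 (-0.22), Tmeff2 (-0.24) and Olfr661 -0.35, Vmn2r102 -0.27, Speer4d -0.26, Pramel37 -0.25 and Olfr469 -0.25. limma called 305 genes, 189 higher and 116 lower (8 without a symbol), and 541 with the receptor score in the model. In batch 2 alone 7 genes were called, Fgd2 0.34, Zmynd15 0.30, Rilpl2 0.20, Prrg2 0.17 and Acot8 0.15 upwards and the cholesterol synthesis gene Msmo1 (-0.32) and Ufl1 (-0.20) downwards. In batch 1 alone the deposited table gave 2. The slope of Tpsb2 was 0.0269 with no filter on dim probes.

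The slope per A allele over both batches rested on 143 arrays of the deposited table. The sources used here do not say how its batches were made alike or whether genotype was kept in that step. A shift of each probe between batches is taken up by batch in the model, whereas a change of scale is not, and all B homozygous mice were in batch 1. The batch 1 columns of the table alone gave 4860 genes. Itpr2 rose by 0.43 (SE 0.0361, adjusted p = 4.09e-19), and Fgfr1op2 had -0.34 (adjusted p = 2.58e-17), with 16 distal chromosome 6 genes called. The largest rises were the imprinted Dlk1 (1.04), Klra3 (0.81), the airway secretory protein Bpifa1 (0.80) and the gastrokine Gkn2 (0.75), followed by Raet1e, a ligand of a natural killer receptor (0.68), and Cyp2c40 0.77, Cyp2c68 0.73, Kng2 0.73, Ankrd22 0.70 and Klra10 0.68. The lowest slopes of called genes, many of them of the same dim genes, were Pbp2 -1.28, Rerg -1.04, Vmn1r122 -0.85, Vmn1r181 -0.84 and Ssty1 -0.80, Gm10375 -0.78, Klra4 -0.78, Defb26 -0.71 and A2ml1 -0.71 and Ubd, an interferon-induced ubiquitin-like gene, -0.71. limma called 4267 genes, 2258 higher and 2009 lower (127 without a symbol), and 1663 with the receptor score in the model. Within batch 2 the slope is the difference of A homozygous and heterozygous tumours given above.

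Between the batches, the deposited table holds nearly equal means for each probe, so the test of batch 2 against batch 1 is void. limma called 0 genes (206 at an unadjusted p under 0.05). For the difference of A homozygous and heterozygous tumours between batches it called 0 as well (520), with Clec2h 0.47, Fbxw13 0.44 and Serpinb9f 0.41 and Ttc24 -0.38, Opa3 -0.35 and Zfp551 -0.36 at the smallest p and an adjusted p of 1.00 for Fbxw13.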

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

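In this part, the tests of the share of tumour cells, of 4 cell type scores together, of the receptor score and of the signs of probes were chosen only after the result was seen.

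For the difference between A homozygous and heterozygous tumours, 3 of the 19 genes called in batch 1 passed limma's test of the interaction with batch, adjusted over those 19 genes alone. For Fbxw13 the batch 2 minus batch 1 difference was 0.435 (SE 0.130, adjusted p = 0.0206), with -0.07 in batch 2 and -0.50 in batch 1, all in the deposited table. For Pik3c2g it was 0.408 (SE 0.135, adjusted p = 0.0291), with -0.17 in batch 2 and -0.58 in batch 1, and for 1 transcript without a symbol 0.292 (SE 0.105, adjusted p = 0.0380). The 19 genes were picked for a large difference in batch 1, which by itself makes smaller differences in batch 2 expected, so these p do not show that the batches differ. Over all genes 0 differed between batches (520 at an unadjusted p under 0.05 by limma).

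Tumours of B homozygous mice differed from A homozygous tumours at 6005 genes, and of 100 splits of the arrays 1, the real one, gave as many (highest other 1). This argues against chance for the count, but the splits did not keep slides together and were not adjusted for their number. Macrophage and T and NK cell scores moved apart by 1.19 (SE 0.204). This argues against a lower share of tumour cells that raises all other cell types alike. A lower share with an uneven makeup of the other cells was not tested and stays open. With endothelial and alveolar type 1 scores in the model, 1610 genes were called (1399 of them among the 6005), more than in any other split. Scores of few genes follow a share of adjacent lung only in part, so this cannot exclude adjacent lung as the whole cause. With the receptor score in the model 2319 genes outside the receptors were called. The score may follow genomic DNA or background signal only in part, so this cannot exclude such signal as the whole cause. For 937 dim genes lower in A homozygous tumours the median difference went from -0.62 to -0.31 (median SE 0.175 and 0.163) and 25.8% stayed called. With scores of random brighter genes fewer did in 100 of 100 draws. For such genes this signal cannot be told apart from any change that the lower genes share. With vessel, alveolar type 1 and both lymphocyte scores in the model 41 genes were called, and the 5908 that lost the call went from a median absolute difference of 0.38 to 0.13 (median SE 0.111 and 0.114), but 81 of 100 draws of as many random lower genes as scores left as few (median 29.5), so a different makeup of these cells cannot be told apart from any change that the lower genes share. With the tumour number in the model 34 genes followed the A allele (4871 without it), and with genotype in the model 4 followed the tumour number (4947 without it), so neither is singled out and both stay open.

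Genes called between A homozygous and heterozygous tumours lay mostly on chromosome 6 (12 of the 17 with a symbol). A strain variant under single probes would change few probes of a gene, but in the separate mice of batch 2, without the probe of largest change in batch 1, a median of 95.7% of the probes of the 10 genes with 3 or more had the sign of the gene in batch 1 (lowest gene 66.7%, most probes in 10 of 10 genes, sign test p = 0.00195), and 8 of the 10 stayed called in batch 1 (Klra7, not called, had -0.90), which argues against it as the whole cause for these genes as a set. It stays open for Gsg1, which had -0.47 with and -0.13 (SE 0.0805) without that probe, and for the other 2, Pbp2 and Klra4, with 1 probe each. Scan day as a block left 12 of the 12 called, which argues against scan day. Of 100 splits 3 gave as many as 19 genes, the real one included. Few splits thus reached the count, but by splits alone chance is not excluded for it, since the tests of splits were not adjusted for their number. In the separate mice of batch 2, 18 of the 19 genes had the same sign and 11 an unadjusted p under 0.05 by limma. This argues against chance for these genes as a set. The highest other split gave 648, which points to a structure of the samples or to genes that move together, and which of them was not tested. A difference of these transcripts by the haplotype on chromosome 6 goes with the 12 genes kept. It stays a hypothesis, since a variant under many probes of a gene was not tested.

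Gene levels followed the tumour number within genotype over both batches at 305 genes. Of 100 permutations of the number 2 gave as many, the real one included, and the highest other gave 435. Few permutations thus reached the count over both batches, but chance is not excluded for it, since such tests were not adjusted for their number. With T and NK cell, endothelial and alveolar type 1 scores in the model 304 of the 305 stayed called, which argues against a share of these cell types that moves with the number. Of 2139 genes with an unadjusted p under 0.05 in batch 1, 68.7% had the same sign in batch 2, within the range of 31.4% to 71.9% over 99 permutations (median 49.9%, 1 as high), so a chance relation in one batch that the other does not share stays open. No other biological explanation was tested.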

How the results depend on the processing

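Scan day as a block, fits within scan days, the receptor score, fits without the dimmest array, single batches by tumour number, the pairwise gene lists and slide as a block for gene lists were chosen after the data were seen. The other alternatives were fixed before. Of the named genes, those fixed before kept direction and side of the threshold in 2470 cases, lost the call in 278, gained it in 69 and turned the direction in 14. Those chosen after did so in 845, 662, 9 and 10. For gene lists the numbers were 316, 22, 11 and 2, and 260, 8, 28 and 1. Where no reason is given, the cause was not tested. No paired analysis was possible because the labels number every mouse as a first replicate and pair none. No alternative moved the median change of all genes by over 0.1. The intensity at the 75th percentile, 325 to 1896, and the share of probes above background limit what can be said of dim genes.

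The number of genes that followed the A allele in batch 1, 4871, was 1250 with the receptor score, 34 with the tumour number as a covariate (33 of them shared), 17 without B homozygous mice and 2972 without the probe of largest change, which tested fewer genes. Within scan days, which hold fewer arrays, it was 1 on day 1, 1563 on day 2 and 13 on day 4. Between A and B homozygous tumours, 6005 became 2323 with the receptor score and 0, 1866 and 2765 within days 1, 2 and 4 (limma gave 835 at an unadjusted p under 0.05 on day 1). Between A homozygous and heterozygous tumours, 19 became 12 with no filter, 11 with only probes above background on every array, 8 without the probe of largest change (13 of the 19 could be tested, the other 6 have 1 probe), and 0, 1, 0 and 3 within days 1 to 4 (139 and 536 at an unadjusted p under 0.05 on days 1 and 3). Between heterozygous and B homozygous tumours, 4088 became 1438 with the receptor score and 0, 0 and 1675 within days 1, 2 and 4 (805 and 3823 on days 1 and 2). In batch 2, the mean over probes gave 2 genes in place of 0. Over both batches, the 4267 genes by A allele became 1663 with the receptor score.

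The deviation from additivity, 187 genes, was 51 with quantile normalization, 112 with normexp, 113 with no filter, 54 with only probes above background on every array, 319 with the mean over probes, 38 with the brightest probe and 23 in the deposited table. It was 462 and 620 with slide as a fixed and a random block, 344 with scan day as a block, 0 with the receptor score (2084 at an unadjusted p under 0.05), 0 without the dimmest array (2717), and 0, 0 and 5 within days 1, 2 and 4 (302 and 2001 on days 1 and 2).

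The 4 genes by tumour number in batch 1 with genotype in the model became 9 with quantile normalization, 1 with normexp, 1 with no filter, 2 with only probes above background on every array, 2 with the mean over probes, 0 with the brightest probe (2645 at an unadjusted p under 0.05), 2 in the deposited table, 0 with slide as a fixed block (1594), 7 with scan day as a block, 46 with the receptor score, 0 with the number untransformed (1685), 65 with its rank, and 0, 0 and 0 within days 1, 2 and 4 (1442, 366 and 1613). Without genotype, 4947 became 2683 with slide as a fixed block, 2036 with the receptor score, and 0, 98, 0 and 2026 within days 1 to 4. The difference of slopes, 0 genes, gave 428 within day 4. Over both batches, 305 became 541 with the receptor score, 7 in batch 2 only and 2 in batch 1 only. Lists called by A allele, 9, became 0 with an estimated correlation and 14 within day 4; the 5 lists by tumour number and the 6 of batch 2 became 0 and 0 with an estimated correlation. The difference of 5.52 tumours between A homozygous and heterozygous mice was 3.66 in batch 2 only and did not pass the test there, with fewer mice.

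Some directions turned. With only probes above background on every array and with the brightest probe alike, Casc1 had -0.0894 per A allele and -0.20 between A and B homozygous tumours, and Klra7 0.0366 between A homozygous and heterozygous tumours. With the brightest probe Alb had -0.17 per allele and -0.39 between A and B homozygous tumours, Stk38l had 0.41 in the latter, Tmem161a -0.0570 between A homozygous and heterozygous tumours and Golt1b 0.0106 between heterozygous and B homozygous tumours. These genes have probes of unlike change, since the alternatives replace only the probes. With the receptor score Slco1b2 had 0.14 between A and B homozygous and 0.00055 between heterozygous and B homozygous tumours. Within day 1 Ldhb had -0.0395 per allele and -0.0250 between A and B homozygous tumours and Nrn1 -0.18 by tumour number. Within day 2 Rep15 had -0.00779 per allele and -0.0577 between A and B homozygous tumours, and within day 3 Spag11b, Ypel4 and Klra3 had -0.50, -0.48 and -0.26 by tumour number without genotype. Ldhb had -0.0737 per allele with the tumour number as a covariate, Tmtc1 0.0155 without B homozygous mice, and Tpsb2 0.0269 by tumour number over both batches with no filter. Of the lists by tumour number, oxidative phosphorylation turned in camera with quantile normalization (mean 0.00312) and normexp (mean 0.00307), though its mean stayed above 0, and T and NK cell had 0.0334 with slide as a fixed block.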

Other observations

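In this part the fibroblast genes named without a call were chosen after their values were seen, and the tests of splits were set before their results were seen.

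Some fibroblast genes and 2 MHC class II genes differed between A and B homozygous tumours, but neither list passed camera. Of 16 fibroblast and matrix genes 7 were lower in A homozygous tumours and 0 higher (7 adjusted over the list alone), and 5 were lower (6) with the receptor score in the model. The elastic fibre gene Mfap4 differed by -1.55 (SE 0.259, adjusted p = 5.27e-06), the methyltransferase Inmt by -1.50, the lung fibroblast factor Tcf21 by -1.26 and the growth factor receptor Pdgfra by -0.78. The collagens Col1a1 and Col1a2 had 0.15 (SE 0.132) and -0.075 (SE 0.126) and were not called. Camera gave an adjusted p of 0.0555 for this list and 0.124 for MHC class II presentation. Of 11 MHC class II genes the 2 lower ones were H2-Ob (-1.52) and H2-Oa (-1.46), a pair known from B cells, and the scores of that list and of B and plasma cells were among those higher in B homozygous tumours (MHC class II -0.38, B and plasma cell -1.11). The T and NK cell score spread more within B homozygous tumours (SD 0.915, n = 13) than within A homozygous tumours (SD 0.444, n = 41); the difference in spread was not tested.

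Metabolic genes higher in A homozygous tumours included fatty acid synthase Fasn (0.50, adjusted p = 6.50e-05), malic enzyme Me1 (0.64), catalase Cat (0.55), lactate dehydrogenase Ldha (0.44) and the ATP synthase subunit Atp5a1 (0.32). Of the lists, cholesterol and fatty acid synthesis had 4 of 22 higher and 2 lower, hypoxia and glycolysis 7 of 23 higher and 3 lower, and oxidative phosphorylation 9 of 27 higher and 3 lower. Camera gave adjusted p of 0.269, 0.0387 and 0.0387, and adjusted p of 0.737, 0.491 and 0.737 with an estimated correlation. With the receptor score in the model 5, 2 and 1 genes of these lists were higher, and 2 oxidative phosphorylation genes were lower.

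Other splits of the samples, 100 for each test with the real one included, bear on the remaining counts. For the genes by A allele in batch 1, 1 split gave as many (4871, highest other 581). It was 1 for A against B homozygous tumours (6005, highest other 1), and for heterozygous against B homozygous tumours 1 (4088, highest other 164). For the deviation from additivity it was 3 (187, highest other 308), for distal chromosome 6 genes with 2 or more probes and most of them called 1 (12, highest other 0) and for the A allele over both batches 1 (4267, highest other 338). For the tumour number in batch 1, 1 permutation gave as many genes with genotype in the model (4, highest other 2) and 1 without (4947, highest other 2). For the deviation from additivity other splits gave as many, and the 4 genes by tumour number lay close to the highest other. Chance is not excluded for either of them. For the other counts no other split gave as many, which argues against chance for the counts as such and says nothing of single genes. These splits did not keep slides together and were not adjusted for their number. The 187 genes became 0 by limma without the dimmest array (2717 at an unadjusted p under 0.05) and 0 with the receptor score in the model (2084), and none of the 4 genes by tumour number passed the test in batch 2.

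Chance could not be excluded for the gene lists: 43 splits gave as many lists by A allele (9, highest other 18), 74 permutations as many by tumour number in batch 1 (5, highest other 18) and 46 as many in batch 2 (6, highest other 14). For counts of 0 genes every split gave as many, that is 100 each: the slopes of A homozygous and heterozygous mice (highest other 280), A homozygous against heterozygous tumours in batch 2 (highest other 2), batch 2 against batch 1 (highest other 3) and batch by genotype (highest other 288). The difference of the B homozygous effect on scan day 1 from the other days was tested as well: limma called 0 of 17315 genes (1139 at an unadjusted p under 0.05), with 100 permutations of the scan days giving as many and a highest other of 711. The splits that called 280, 288 or 711 genes point to a structure of the samples or to genes that move together, and which of them was not tested. Arrays of a slide had a consensus correlation of 0.213 to 0.246 in the batch 1 fits, and the splits did not keep slides together.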
